A study of Mus musculus with 8 samples.

How the data were processed

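Gene expression was measured in cultures of mouse sacral neural crest cells on 8 Affymetrix Mouse Gene 1.0 ST arrays, 4 from embryos homozygous for the Dom allele of Sox10 (Dom/Dom) and 4 from wild-type embryos. Per the labels' protocols, the neural tube below somite 24 of embryos at embryonic day 9.5 was cultured in medium with 10% serum, the explant was taken away after 24 hours, and RNA was extracted from the cells that had left it. Labelled probe was made from 250 ng of total RNA. Genotype and replicate number were taken from the sample titles. No label says that the replicates of a genotype came from separate embryos or litters, so p-values measure the spread between these samples, which may be partly technical.

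The deposited values are log2 expression per probe set and array. RMA and Partek are named in the submitters' processing notes, with versions and settings not given in the sources used here. RMA corrects background, normalises between arrays and summarises the probes of a probe set on the log2 scale, and it compresses differences of dim probe sets. The values came without detection calls, so signal over background could not be assessed per gene. The number of arrays limits the precision.

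The table used here held 16381 probe sets, with identifiers from 10338001 to 10436752, which is part of the array. Of these, 7416 were paired with 1 gene symbol by the platform annotation, 509 with several and 8456 with none. Probe sets with 1 symbol were kept, and a gene with several of them (308 genes) was represented by the one with the highest mean over all 8 arrays, which left 6855 genes. Symbols and chromosomes were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, which matched 6829 genes; the other 26 kept the platform's symbol. Of the genes tested, 6708 (97.9%) lay on chromosomes 1 and 10 to 16. Genes outside this part of the array were not analysed here, among them the X-inactivation and Y-linked genes of a list meant to describe the sex of the embryos, of which 0 were measured. Array medians lay between 8.60 and 8.78. No array was identical to another, and correlations of levels between arrays ran from 0.985 to 0.998.

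Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term, two-sided), with Benjamini-Hochberg adjustment over the 6855 genes and a threshold of 0.05. Differences are Dom/Dom minus wild type on the log2 scale. Sox10 was also tested with an exact permutation test and, by pairs, with an exact sign-flip test. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists with at least 3 measured genes; the counts of members past the threshold were also adjusted over the list alone. The 34 lists covered neural crest specifiers, glia and Schwann cells, enteric progenitors, melanocytes, sensory and sympathetic neurons, general neuronal genes, neural tube, tail bud, somite and lateral mesoderm, endothelium, blood and macrophages, surface ectoderm and epithelium, smooth muscle, fibroblast collagens, migration matrix, integrins, cadherins, proteases, guidance, Eph and ephrin genes, actin and focal adhesion, cell cycle, p53 and apoptosis, immediate early genes, amino acid and unfolded protein stress, hypoxia and glycolysis, cholesterol synthesis, interferon, targets of Wnt, BMP and Notch, targets of FGF, hedgehog and retinoic acid, posterior and anterior Hox genes, the neighbours of Sox10, and sex. The lists, the tests of genes and lists above other than the sign-flip test, the alternatives listed in advance and the rule for named genes were fixed before the data were examined, and the tests of explanations were written after a first fit or later. That rule took Sox10, the 12 largest falls and the 12 largest rises among genes past the threshold whose groups did not overlap, up to 4 members past the threshold per list and, in lists without one, the 2 members with the largest difference. Any other gene named was chosen after its values were seen.

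The 2 genotypes share replicate numbers. Whether these pair the samples was checked from the deviations of each array from its genotype's mean. Same-numbered arrays correlated at 0.47, 0.58, 0.61 and 0.67 for replicates 1 to 4, each above 0.1, so the numbers were taken to pair the samples. Differently numbered arrays within replicates 1 and 2 (0.11 and 0.14) and within 3 and 4 (0.38 and 0.21) were also above 0.1, though below the same-numbered values. The limit of 0.1 therefore does not separate pairing from a grouping of replicates 1 and 2 against 3 and 4. This pairing comes from the data, as no label states it. A fit with the replicate number as a block was planned as an alternative, and its values stand with results whose call it changed or whose count it moved by more than 1.5 times.

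The steps were tested on simulated data with the spread of these arrays, in which 100 of the 6855 genes were changed by 1 log2 unit and 100 by 2. The fit without a block recovered 94% and 100% of them, with 0% false calls. The blocked fit recovered 96% and 100%, and 5.77% of its calls were false. Spread was drawn for each gene on its own, without a structure shared between genes, so these rates may not hold for the real arrays. Alternatives listed in advance were filters on dim probe sets, quantile normalisation, median centring, cyclic loess, a trended robust prior, array weights, the block, leaving out each array, all probe sets, the mean of a gene's probe sets, stricter thresholds, and other list tests (an estimated correlation, ranks, and fry). A block for replicates 1 and 2 against 3 and 4, fits within each of these sets of replicates, the blocked fit with each pair left out, and the blocked list test with an estimated correlation were added after seeing the data.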

Results

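The expression of genes in sacral neural crest cells was compared between Sox10 Dom/Dom and wild-type mouse embryos. Neural crest cells are migratory cells of the embryo that form glia, melanocytes and peripheral neurons, and those of the sacral level contribute to the nervous system of the hindgut. Sox10 encodes a transcription factor of these cells, and Dom is a frameshift allele of it. The cells were those that had migrated out of neural tube explants in culture, and each genotype had 4 arrays, numbered as replicates 1 to 4. Of the genes on the array, 6855 were tested, nearly all on chromosomes 1 and 10 to 16, and the counts below refer to these genes.

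**Figure D1:**
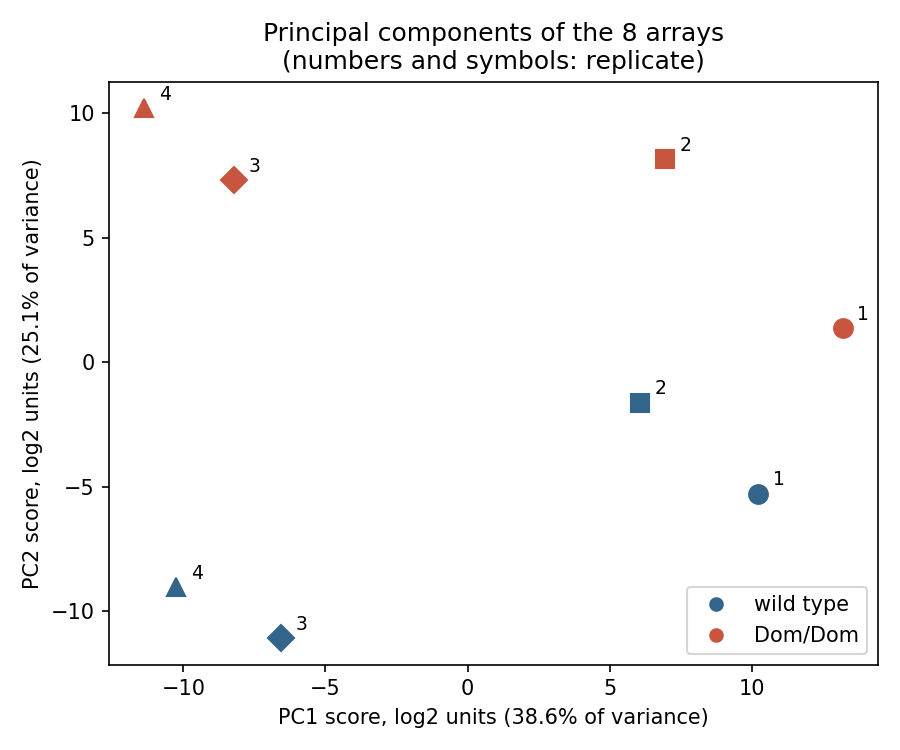
Scores of the 8 arrays on the first and second principal components of the tested genes, in log2 units; colour gives the genotype, and symbols and numbers give the replicate. The first component (38.6% of variance) separates replicates 1 and 2 from replicates 3 and 4 in both genotypes, and on the second (25.1%) each Dom/Dom array lies above the wild-type array of the same number.

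Sox10 itself (probe set 10430458, chromosome 15) was 2.29-fold lower in Dom/Dom cultures. Its level was 10.50 ± 0.40 log2 units (SD, n = 4) in Dom/Dom and 11.69 ± 0.18 (SD, n = 4) in wild type, a difference of -1.20 with a standard error of 0.18 (limma adjusted p = 0.0168; 0.0312 with the replicate block). It was lower in 4 of 4 pairs of same-numbered arrays, by log2 differences of -1.69, -0.52, -1.37 and -1.20. An exact two-sided permutation test that ignores the pairs gave p = 0.0286, and an exact sign-flip test of the 4 pairs gave p = 0.125, each the smallest that such a test allows here. The Dom transcript is still made, so this level does not check the genotype labels. Without any 1 of the 4 arrays of replicates 3 and 4, the adjusted p of Sox10 lay between 0.0607 and 0.0762.

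In all, 33 genes differed between the genotypes, 28 lower and 5 higher in Dom/Dom, and the 16 that differed by at least 2-fold were all lower. The largest fall was that of Cdh19, a cadherin of Schwann cell precursors, which was 19.1-fold lower (6.87 ± 0.66 in Dom/Dom against 11.13 ± 0.86 in wild type, SD, n = 4; limma adjusted p = 0.00166). Dct, an enzyme of melanin synthesis, was 5.77-fold lower (adjusted p = 0.00152). Lama4, a laminin chain of basement membranes, was 5.64-fold lower (adjusted p = 0.00152), and Slitrk6, a neuronal transmembrane protein, 4.59-fold lower (adjusted p = 0.00745). Pmel, which forms the fibrils of melanosomes, was 3.59-fold lower (adjusted p = 0.00152), and Erbb3, a neuregulin receptor of the glial lineage, 2.97-fold lower (adjusted p = 0.0214). Further falls were those of the Wnt pathway inhibitor Nkd2 (2.62-fold), the mTOR inhibitor Deptor (2.47-fold), the amino acid transporter Slc6a15 (2.44-fold), the neurturin receptor Gfra2 (2.33-fold) and Cnp, an enzyme of myelinating glia (2.30-fold), with adjusted p between 0.00298 and 0.0336.

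The 5 genes that rose changed less than each of the 12 largest falls, which are those named above. The iron exporter Slc40a1 was 1.94-fold higher in Dom/Dom (9.74 ± 0.28 against 8.78 ± 0.30, SD, n = 4, limma adjusted p = 0.0412), and the BMP and Wnt antagonist Sostdc1 was 1.82-fold higher (adjusted p = 0.0143). Parp8 rose 1.70-fold (adjusted p = 0.0322), Pappa2, a protease of IGF-binding proteins, 1.51-fold (adjusted p = 0.0146), and Ift27, a component of intraflagellar transport, 1.48-fold (adjusted p = 0.0265). Pappa2 had 3 probe sets, with differences of 0.59, 0.46 and 0.34. All 33 genes had groups that did not overlap, as did 3.78% of all tested genes, where chance gives 2.86%.

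With the replicate block the count was 103 genes, 31 higher and 72 lower, of which 30 were among the 33. The 3 genes lost, chosen by that loss, were Igsf11 (blocked adjusted p = 0.0652), Cmtm5 (0.0533) and Gas7 (0.0566). The count without a block rested on replicates 3 and 4: leaving out 1 of their 4 arrays gave 10 to 12 genes, 0 of them higher, so each of the 5 rises lost its call there, as did Sox10. Without wild-type replicate 2 the count was 51. Tested over all probe sets the count was 4, with 0 higher, and with array weights it was 190, 54 higher and 136 lower.

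**Figure D2:**
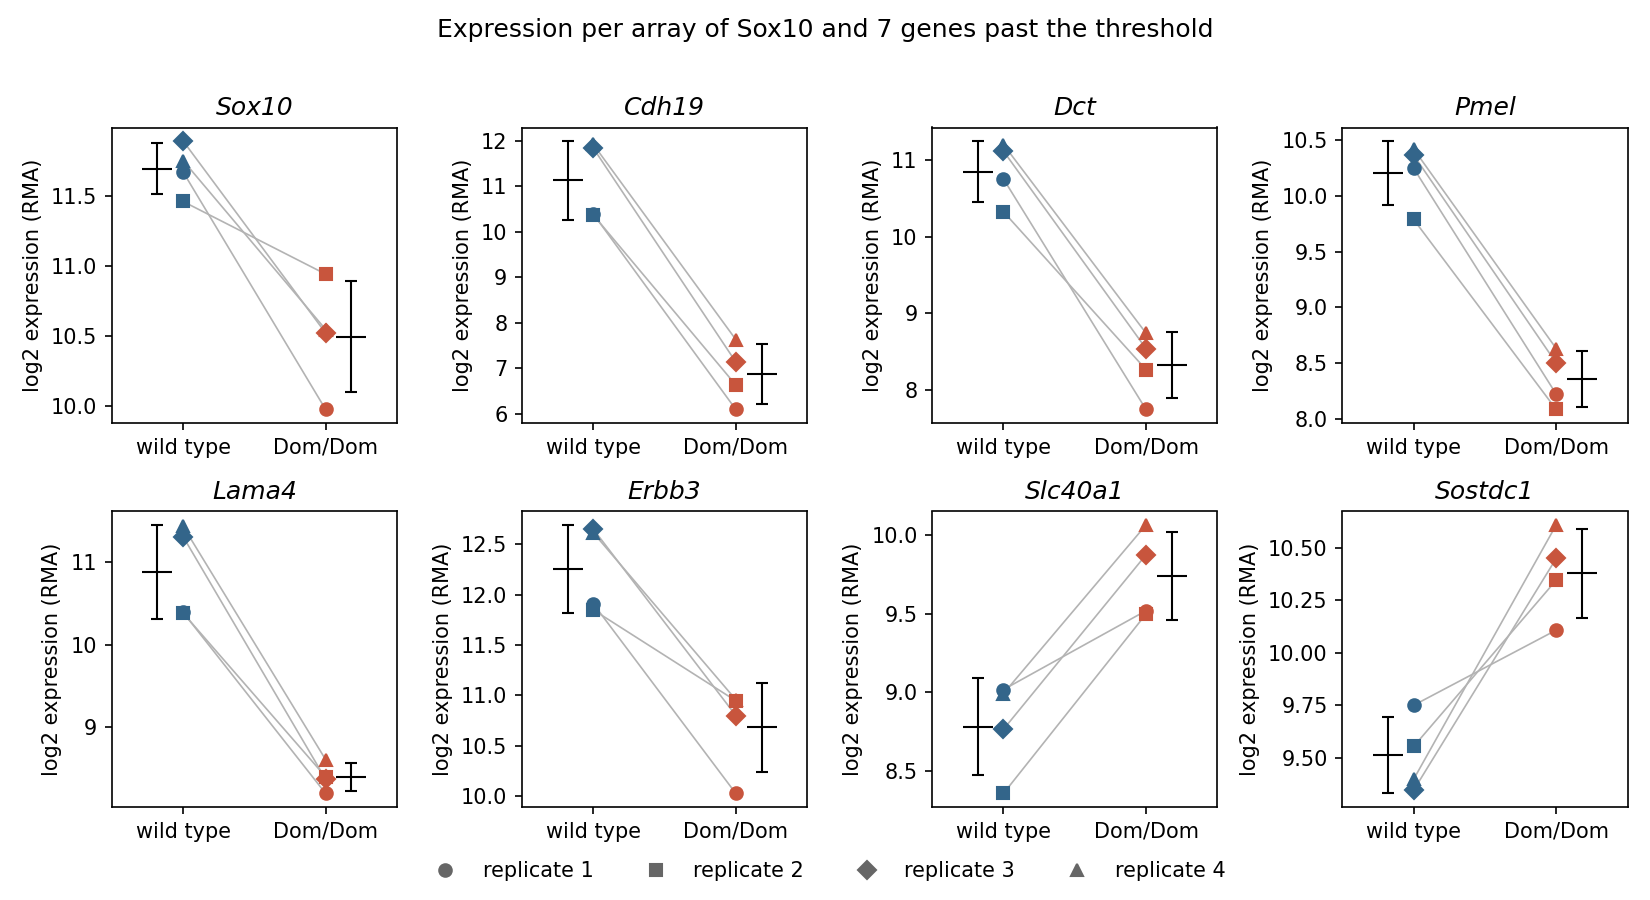
Log2 expression per array for Sox10 and 7 genes past the threshold, with symbols for replicates, grey lines joining same-numbered arrays, and black bars for the mean and SD of 4 arrays. Every Dom/Dom array lies below every wild-type array for Sox10, Cdh19, Dct, Pmel, Lama4 and Erbb3, and above for Slc40a1 and Sostdc1; vertical axes differ between panels and do not start at 0.

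Genes of glia and Schwann cells, a list that holds many known SOX10 targets, were lower as a group in Dom/Dom. Of 12 measured members, 5 fell, 1 rose and 6 did not pass; adjusted over the list alone, 6 fell and 1 rose. With the replicate block, 4 fell and 1 rose, as Gas7 was lost. Those that fell without it were Cdh19, Erbb3, Cnp, Gas7 and Adgrg6, an adhesion receptor needed for myelination (10.77 ± 0.19 against 11.75 ± 0.20, SD, n = 4; limma adjusted p = 0.00745), and the one that rose was Sostdc1. The list's mean difference was -0.76 and its median -0.34 (camera adjusted p = 1.63e-07). It was the single list of 33 that passed with an estimated correlation (adjusted p = 0.0378), though it did not with that and the block (adjusted p = 0.619). Fabp7, the glial fatty acid binding protein, stood at 13.99 ± 0.14 and 14.07 ± 0.12 (SD, n = 4).

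Of 3 measured melanocyte genes, 2 fell, Dct and Pmel, and the same 2 fell when adjusted over the list alone. The mean difference was -1.46 (camera adjusted p = 1.63e-07; adjusted p = 0.0799 with an estimated correlation). Beside these lists, somite and lateral mesoderm genes had a mean difference of 0.18 and epithelial genes one of -0.20, with adjusted p = 0.488 and 0.504 with an estimated correlation.

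Of 14 measured neural crest specifiers, 0 passed over all genes, and adjusted over the list alone 3 fell. With the replicate block 2 fell over all genes, Tfap2a and Cdh6. The list's median difference was 0.02 and its mean -0.12, and the test pointed down without passing (camera adjusted p = 0.190). The neurotrophin receptor gene Ngfr stood at 10.98 ± 0.68 in Dom/Dom and 11.93 ± 0.08 in wild type (SD, n = 4; limma adjusted p = 0.267), and Tfap2a differed by -0.50 (adjusted p = 0.108; 0.0418 with the replicate block) and Cdh6 by -0.41 (adjusted p = 0.376; 0.0310 with the block). Of 5 enteric progenitor genes 0 passed over all genes and 1 fell adjusted over the list alone, the endothelin receptor Ednrb (difference -0.92, adjusted p = 0.0718); the list did not pass (camera adjusted p = 0.119).

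Without the block no single member passed the threshold, and the neuronal lists were shifted down. With the block the sensory and sympathetic list stayed shifted down (camera adjusted p = 0.0249), but the general neuronal list did not pass. In pair 1 they ran the other way: 7 of 7 general neuronal genes and 5 of 6 sensory and sympathetic genes were higher in Dom/Dom (mean differences 0.59 and 0.22), against means from -0.57 to -0.41 in pairs 2 to 4. Sensory and sympathetic genes (6 measured, mean difference -0.30) passed with camera adjusted p = 0.0102, but with adjusted p = 0.488 with an estimated correlation. Their largest differences were those of Isl1 (-0.68, limma adjusted p = 0.591) and Pou4f1 (-0.64, adjusted p = 0.201; 0.00744 with the replicate block), both transcription factors of sensory neurons, and adjusted over the list alone 1 fell. General neuronal genes (7 measured, mean -0.22, 0 adjusted over the list alone) gave camera adjusted p = 0.0273, with adjusted p = 0.578 with an estimated correlation and 0.172 with the replicate block.

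Among adhesion and matrix genes, 1 of 10 cadherins and their partners fell, Cdh19, and 2 fell adjusted over the list alone; with the replicate block 2 fell over all genes, Cdh19 and Cdh6. The list's mean was -0.56 and its median -0.11 (camera adjusted p = 0.00270; adjusted p = 0.117 with an estimated correlation). Of 16 genes of the migration matrix, 1 fell, Lama4; adjusted over the list alone, 3 fell and 1 rose. With the replicate block 3 fell over all genes, Lama4, Vcan (difference -0.59, adjusted p = 0.118; 0.0269 with the block) and Has2 (-0.50, adjusted p = 0.377; 0.0459 with the block). The list's mean was -0.18 and its median -0.05, with Lama4 itself at -2.50. The list gave camera adjusted p = 0.0454, with adjusted p = 0.578 with an estimated correlation and 0.124 with the replicate block. Guidance genes (8 measured) were shifted up by a mean of 0.12 (adjusted p = 0.0273; adjusted p = 0.488 with an estimated correlation), led by Sema5a at 0.32 (limma adjusted p = 0.360). Actin and focal adhesion genes (14 measured) were shifted up by 0.08 (camera adjusted p = 0.0105; adjusted p = 0.578 with an estimated correlation), and their largest difference was that of Diaph3 (0.31, limma adjusted p = 0.652). In these last 2 lists 0 members passed, and 0 adjusted over the list alone. Integrins (10 measured, camera adjusted p = 0.342), proteases and inhibitors (9 measured, adjusted p = 0.841; 1 rose and 1 fell adjusted over the list alone) and Eph and ephrin genes (4 measured, adjusted p = 0.471; 1 fell adjusted over the list alone) did not pass. The proteases' mean was -0.004 and their median 0.03, and the test pointed up.

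Smooth muscle genes were shifted up in Dom/Dom, with 8 of 8 measured members above 0 and a mean difference of 0.21 (camera adjusted p = 0.000732; adjusted p = 0.209 with an estimated correlation). Of these, 0 passed over all genes and 2 rose adjusted over the list alone: Myocd, a coactivator of smooth muscle genes (difference 0.63, limma adjusted p = 0.353), and Des, which encodes desmin (0.36, adjusted p = 0.371). Somite and lateral mesoderm genes (10 measured) gave camera adjusted p = 0.0152, with adjusted p = 0.488 with an estimated correlation; 0 passed over all genes and 1 rose adjusted over the list alone, the myogenic factor Myf5 (0.60, limma adjusted p = 0.201). Prrx1 differed by 0.44 (adjusted p = 1.00; 0.0339 with the replicate block). Fibroblast collagens (9 measured, camera adjusted p = 0.119) did not pass.

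Of the lists for other tissues, surface ectoderm and epithelial genes (12 measured, 11 below 0, mean -0.20) were shifted down, with camera adjusted p = 0.00270 and adjusted p = 0.504 with an estimated correlation; 0 members passed, and 0 adjusted over the list alone. Krt8, a keratin of simple epithelia, stood at 12.12 ± 0.21 and 12.61 ± 0.23 (SD, n = 4; limma adjusted p = 0.232; 0.0164 with the replicate block). Neural tube (5 measured, camera adjusted p = 0.342), tail bud (5 measured, 0.745), endothelial (4 measured, 0.786) and blood and macrophage lists (6 measured, 0.402) did not pass. The embryonic globin gene Hba-x was abundant and varied between arrays of one genotype, at 12.02 ± 0.90 in Dom/Dom and 12.71 ± 0.91 in wild type (SD, n = 4).

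Cell cycle genes (10 of 10 above 0, mean 0.10) and immediate early genes (10 of 10 above 0, mean 0.14) were shifted up, with camera adjusted p = 0.0135 and 0.00256. With an estimated correlation their adjusted p were 0.578 and 0.488, and in each list 0 members passed over all genes and 0 adjusted over the list alone. The lists for p53 and apoptosis (11 measured, camera adjusted p = 0.124), amino acid and unfolded protein stress (7 measured, 0.126), hypoxia and glycolysis (11 measured, 0.810), cholesterol synthesis (7 measured, 0.630) and interferon (4 measured, 0.510) did not pass, nor did targets of Wnt, BMP and Notch (10 measured, 0.471) and of FGF, hedgehog and retinoic acid (11 measured, 0.190). In these 2 target lists 1 gene each rose adjusted over the list alone, the Wnt feedback inhibitor Notum (difference 0.61, limma adjusted p = 0.0512) and Etv1 (0.34, adjusted p = 0.164; 0.0339 with the replicate block). The Wnt, BMP and Notch list had a mean of 0.04 and a median of -0.02. In the amino acid stress list Ddit4 differed by -0.34 (adjusted p = 0.642; 0.0353 with the replicate block).

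Posterior Hox genes (7 measured, camera adjusted p = 0.942, mean -0.01 with the test pointing up) and anterior Hox genes (11 measured, adjusted p = 0.199) did not pass. Of the 28 measured genes listed as neighbours of Sox10, 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.942). Without the block, lists above with no count of their own had 0 members past the threshold, over all genes or adjusted over the list alone. Adjusted over the list alone with the replicate block, 3 enteric progenitor genes fell and 1 rose, 4 somite genes rose, 2 sensory and sympathetic genes fell, 2 epithelial genes fell, 4 cadherins fell, 4 migration matrix genes fell and 2 rose, 3 smooth muscle genes rose and 2 proteases fell. By that count 2 fibroblast collagens, 2 guidance genes, 2 p53 and apoptosis genes and 1 hypoxia gene rose, 2 amino acid stress genes and 1 target of Wnt, BMP and Notch fell, and of the listed neighbours of Sox10 4 rose and 3 fell. Across all lists, 13 of 33 passed with the preset correlation and 11 with the replicate block, against 1 with an estimated correlation and 0 with that and the block.

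Leaving out each of the 8 arrays in turn, with the preset correlation, the glial, melanocyte, cadherin, smooth muscle and immediate early lists passed in 8 of 8 fits; over all arrays with an estimated correlation, the glial list alone passed, and the others gave adjusted p = 0.0799, 0.117, 0.209 and 0.488. The sensory and sympathetic list did not pass without wild-type replicate 4 (highest camera adjusted p = 0.0732), nor the epithelial list without wild-type replicate 1 (0.0621). The somite and actin lists were lost without wild-type replicate 2 or Dom/Dom replicates 3 or 4 (up to 0.233 and 0.139), and the cell cycle list without wild-type replicate 1 or Dom/Dom replicates 2 or 4 (up to 0.144). The migration matrix and guidance lists were lost without Dom/Dom replicates 1 or 2 or wild-type replicates 1, 3 or 4 (up to 0.394 and 0.444). The general neuronal list passed only without an array of replicate 1 (up to 0.411 in the other fits). Of the 13 lists, 7 had a mean of the opposite sign in 1 of 4 pairs: beside the neuronal lists, these were actin (-0.12), immediate early (-0.11), cell cycle (-0.03) and smooth muscle genes (-0.001) in pair 1, and guidance genes (-0.003) in pair 3.

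**Figure D3:**
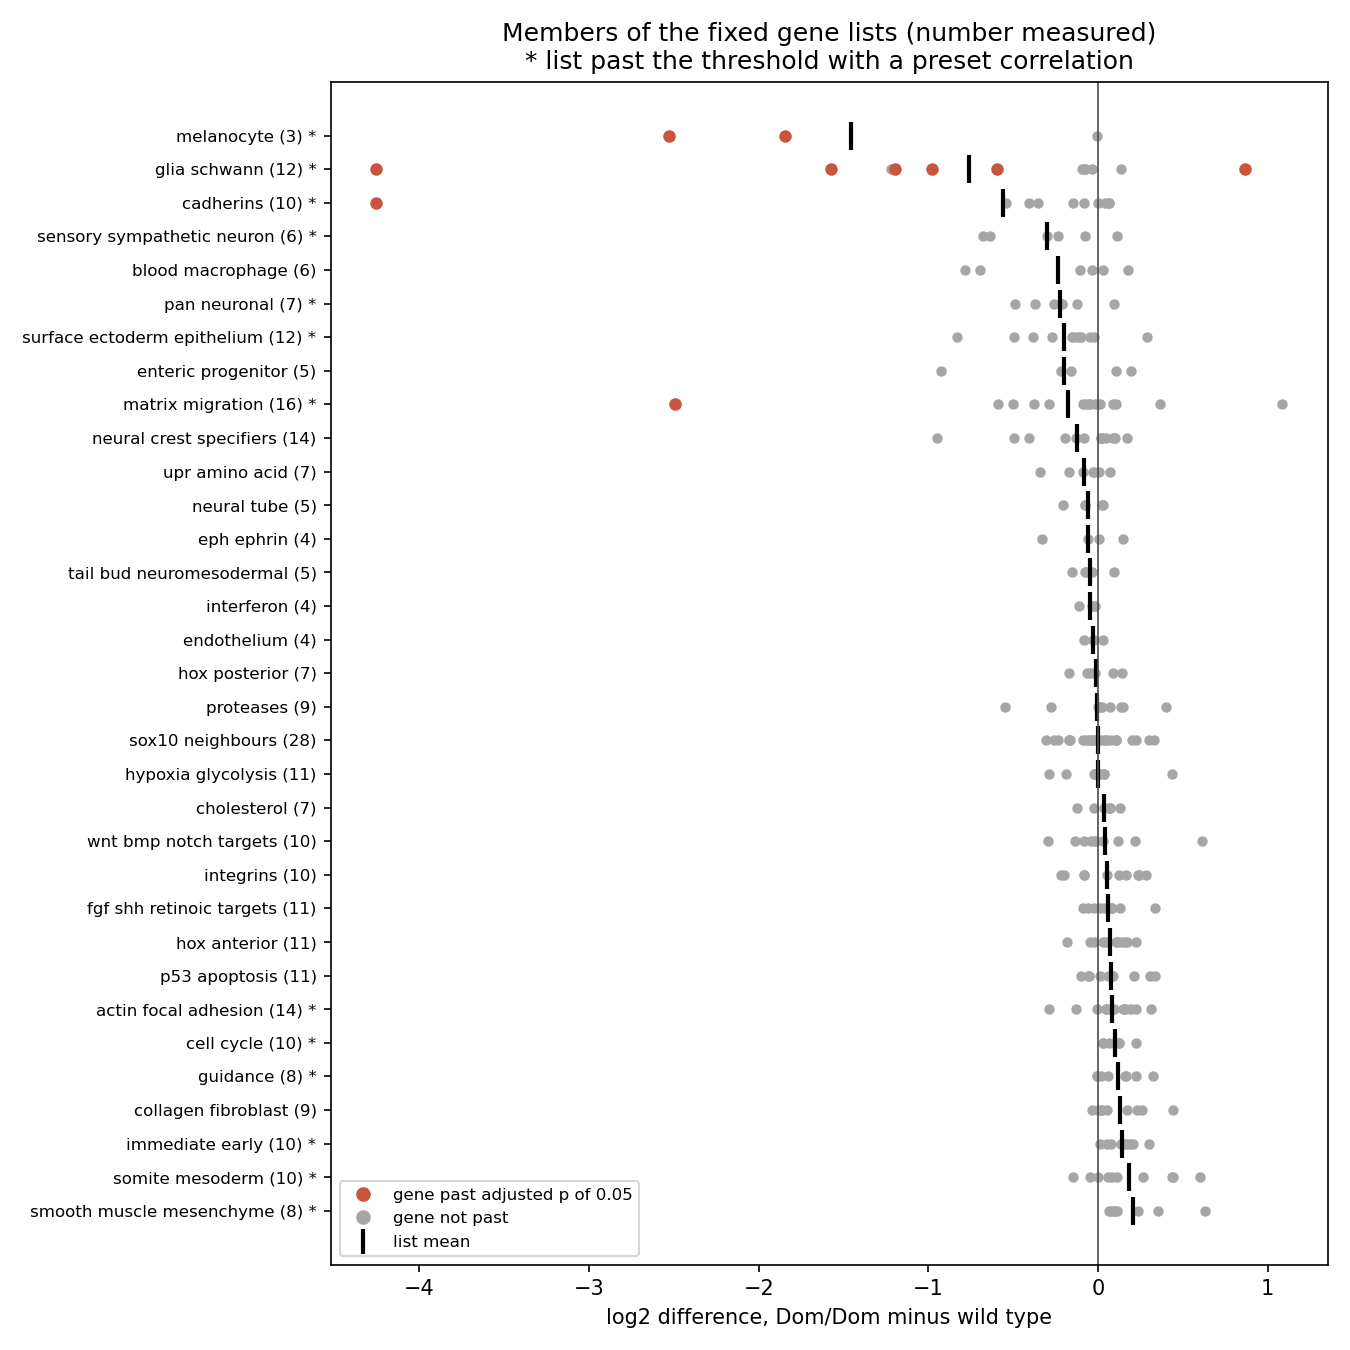
Log2 difference (Dom/Dom minus wild type) of each measured member of the 33 tested lists, with the number measured beside each name; red points passed the adjusted threshold, grey points did not, and black bars are list means. Red points stand in the glial, melanocyte, cadherin and migration matrix lists only, and an asterisk marks the 13 lists past the threshold with the preset correlation.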

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

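The arrays of each genotype were searched for a single value far from the other 3, for the named genes, the list means and the array medians. Of 220 sets of 4 arrays, 11 held such a value, and 11 are expected by chance. Among called genes, Erbb3 was low in Dom/Dom replicate 1 (10.03, against 10.80 to 10.96 in the other 3 Dom/Dom arrays), and Ift27 was high in Dom/Dom replicate 2 (10.26, against 9.97 to 10.01). Cntn2 was high in Dom/Dom replicate 1 (11.14, against 10.10 to 10.27).

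In wild-type replicate 1, Itga3 (10.40, others 9.67 to 9.69), Il17rd (10.30, others 9.85 to 9.88) and the mean of the neural crest specifier list (11.69, others 11.65 to 11.66) were high, and Hoxc9 was low (11.19, others 11.47 to 11.51). In wild-type replicate 2, Plk2 (11.34, others 11.76 to 11.83), Ndrg1 (9.82, others 10.30 to 10.32) and the mean of the actin and focal adhesion list (11.79, others 11.91 to 11.93) were low. Sema5a was low in wild-type replicate 3 (9.84, others 9.97 to 10.00).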

How the results depend on the processing

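The blocks for sets of replicates, the fits within them, the blocked fits without a pair and the blocked list test with an estimated correlation were chosen after seeing the data. Cdh19, Dct, Lama4 and Pmel kept their direction and call under every alternative run on them (22 or 23 each), and the 33 called genes kept their direction in each fit that tested them (31 and 23 of them after the filters on dim probe sets). The groups of all 33 did not overlap, so only the fits with another normalisation could have turned a direction. The kept directions in the other fits were fixed by that and are no test of it. The count of 33 genes stayed within 1.5 times under dim-probe filters, quantile normalisation, median centring, cyclic loess, a trended robust prior, the mean of a gene's probe sets and a 1.5-fold minimum (25 to 47 genes). It moved with array weights (190 genes, 54 higher and 136 lower) and the replicate block (103, 31 and 72). It also moved with all probe sets (4, all lower, 0 higher) and an adjusted p below 0.01 (11, all lower, 0 higher). The last of these is a stricter threshold. The fit over all probe sets adjusts over more tests and also estimates the variance prior anew, and these 2 changes were not told apart. Median centring gave 43 lower, and leaving out the dimmest 50% gave 3 higher and 8 lists. Leaving out 1 array gave 10 to 51 genes, with 0 to 12 higher and 10 to 47 lower, and Sox10 differences from -1.34 to -1.02. The block for replicates 1 and 2 against 3 and 4 gave 116 genes (30 higher, 86 lower). Replicates 1 and 2 alone gave 4 genes (0 higher, 4 lower), 6 lists and a Sox10 difference of -1.11 that did not pass (limma adjusted p = 0.746, where that p ran from 0.000352 to 0.746 over all alternatives), and replicates 3 and 4 alone 352 genes (107 and 245). The blocked fit without pair 1 gave 475 genes (201 and 274), without pair 2 112 (19 and 93), without pair 3 15 (2 and 13) and without pair 4 13 (3 and 10). The last 2 gave 8 lists each, and Sox10 differences of -1.14 and -1.19 that did not pass. Of 33 lists, 13 passed as tested, 1 with an estimated correlation, 0 with that and the block, 7 on ranks and 2 with fry. Among the named genes and the lists, the replicate block changed no call other than those given beside it in the results. Fewer samples enter the fits that leave arrays out; for the other changes the cause was not tested.

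Over the alternatives, list results kept direction and side of the threshold in 711 cases, lost the call in 109, gained it in 12 and turned direction in 52; for named genes these were 1512, 80, 99 and 15. The general neuronal list was the one called result that turned (mean 0.059 in replicates 1 and 2 alone); the rest had passed in neither fit and lay near 0. The direction of a list is that of its test, so its mean can keep its sign. Turned list means were as follows. Sox10 neighbours gave -0.039 with quantile normalisation, -0.026 with cyclic loess, 0.0072 with array weights, -0.0028 with the block for replicates 1 and 2 and on ranks, 0.0033 and -0.0088 within the sets of replicates, and 0.027 and -0.0038 blocked without pair 1 or 4. Posterior Hox genes gave -0.012 with either block, with the blocked estimated correlation and on ranks, -0.10 in replicates 1 and 2, and -0.041 and -0.043 blocked without pair 3 or 4. Hypoxia genes gave -0.0020 with the block for replicates 1 and 2, 0.0047 in replicates 3 and 4, and 0.035 blocked without pair 1. Cholesterol genes gave 0.0013 with array weights, -0.023 in replicates 3 and 4 and -0.015 blocked without pair 1. Wnt, BMP and Notch targets gave -0.023 without the dimmest 50%, -0.00013 in replicates 1 and 2, 0.027 and 0.024 blocked without pair 2 or 3, and 0.038 on ranks. Tail bud genes gave -0.017 with array weights and proteases -0.044 blocked without pair 2. In replicates 1 and 2 alone, endothelial genes gave 0.0082, fibroblast collagens -0.0024 and interferon genes 0.023, and of named genes Fabp7 0.041, Pecam1 0.045, Mcm6 -0.015 and Fos -0.078. Xaf1 gave 0.011 with array weights, 0.034 in replicates 3 and 4 and 0.013 blocked without pair 1, and Pecam1 0.015 blocked without pair 4. Leaving out 1 array, ranges were -0.075 to 0.080 for posterior Hox genes, -0.11 to 0.046 for tail bud, -0.056 to 0.040 for hypoxia, -0.0090 to 0.075 for cholesterol, -0.048 to 0.036 for Sox10 neighbours, -0.035 to 0.024 for proteases, -0.13 to 0.0072 for Eph and ephrin genes and -0.050 to 0.0049 for endothelium. For genes they were -0.038 to 0.27 for Idi1, -0.069 to 0.025 for Xaf1, -0.30 to 0.038 for Hoxb13 and -0.097 to 0.020 for Pecam1. The values carry no detection calls, so dim genes such as Cdh19 in Dom/Dom (6.87) may lie near background, where a fold is understated.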

Other observations

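The blocked fit brought further genes past the threshold, named here after their values were seen. Rgs5, a marker of pericytes, was 1.86-fold higher in Dom/Dom (blocked limma adjusted p = 0.00358), as were the activin subunit gene Inhba (1.57-fold, 0.00358), Ptgs2 (1.51-fold, 0.0138) and the secreted matrix protein gene Ccdc80 (1.75-fold, 0.0124). Lower were Cthrc1 (2.16-fold, 0.00358), the transcription factor genes Mef2c (2.01-fold, 0.0221) and Alx1 (1.77-fold, 0.00360), and Vcan, which encodes the matrix proteoglycan versican (log2 difference -0.59, 0.0269). Without the block their adjusted p lay between 0.116 and 0.583.

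Of the tests below, those on a wider interval around Sox10, on its neighbours and on the somite against the epithelial list were chosen or reworded after results had been seen; the others were written before their own values were seen, but after a first fit had shown the counts and top genes. Of 12 glial genes 5 fell and 1 rose, and of 3 melanocyte genes 2 fell. With an estimated correlation these lists gave camera adjusted p = 0.0378 and 0.0799. They gave 0.619 each with the block too, where few degrees of freedom leave little power. Of 14 neural crest specifiers 0 passed over all genes, 3 fell adjusted over the list alone, and 2 fell over all genes with the replicate block; the lists were not tested against each other (419 of all tested genes had an unadjusted p below 0.05). If neural crest cells were fewer in Dom/Dom cultures, crest specifiers were predicted to fall about as far as Sox10. With 250 ng of RNA per array, only a lower share of such cells could show. The median difference of the specifiers was 0.0151 (95% bootstrap interval over genes -0.19 to 0.07, 14 genes), above -0.60, which is 50% of the Sox10 difference. That interval leaves out the spread between arrays. Of the 14, 8 lay above 0 and 6 below, with Ngfr, Tfap2a and Cdh6 lowest (-0.95, -0.50 and -0.41), so a lower share is not excluded. If a lower share of crest cells raised all other tissues alike, the somite and epithelial lists would rise together. Their mean differences lay 0.381 apart (95% bootstrap interval over genes 0.18 to 0.60, and t interval over the 4 pairs 0.08 to 0.68). These lists were picked after their means, 0.18 and -0.20, had been seen, so a gap was built in. Other tissues need not change alike, so the gap does not decide whether the share of crest cells was lower. Over 35 genes of other tissues the median was -0.0464 (-0.11 to 0.03), which pools lists that move apart and so decides nothing. A lower share of crest cells and more cells of a single tissue, such as mesoderm, stay open. Also open, and not tested here, is whether the Dom allele lowers glial and melanocyte transcription within crest cells or the share of cells entering those lineages.

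The genes that differed were compared with other splits of the 8 arrays into 4 and 4. The real split gave 33 genes, and 2 of 35 splits gave as many, so chance cannot be excluded by this count alone. The other was replicates 1 and 2 against 3 and 4, with 977 genes, which points to a structure of the samples that no label names; with that structure as a block, genotype gave 116 genes. Among the 8 splits that part all 4 pairs, as the real one does, the highest other count was 4. With the replicate block it was 52 against 103 for the real split, where 1 of 8 splits reached that count. These 8 splits are too few for a share under 0.05. The highest other split was the real one with only the arrays of pair 1 exchanged. It still parts the genotypes in pairs 2 to 4, so it is not a comparison free of genotype. The remaining splits of this kind gave 0 genes in either fit. Among them, those with only pair 2, 3 or 4 exchanged also part the genotypes in the other pairs. Genotype left in a split therefore does not by itself account for the count of 52. Pair 1 stood apart in the blocked fits too, which gave 475 genes without it and 112, 15 and 13 without pairs 2, 3 and 4. Why it did was not tested. For lists, the real split gave 13 and the highest other 11, and 1 of 35 splits gave as many, which excludes chance at 0.05 only if the pairs are set aside. Among the 8 splits that part all pairs the highest other was also 11, from the same split with pair 1 exchanged, and the remaining ones gave 0 to 5. These 8 splits are too few for a share under 0.05.

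Alleles of the strain that carried Dom may travel with it and differ in expression near Sox10. Among 28 measured genes listed as neighbours, 3 passed an unadjusted p of 0.05, against 415 of 6826 other genes (one-sided Fisher's exact p = 0.242). With the replicate block these were 8 of 28 against 941 of 6826 (one-sided Fisher's exact p = 0.0317), as linkage would give. Of the 28, 0 passed the adjusted threshold, but 1700088E04Rik, which lies 2 tested genes from Sox10 and was not on the list, passed it with the block (difference -0.38, limma adjusted p = 0.0433). A wider interval of 50 tested genes on each side was set after Ift27, Cbx7 and Syngr1 had been seen, so its p values partly restate that choice. In it 4 of 100 passed in the blocked fit (Ift27, Cbx7, Syngr1 and 1700088E04Rik), against 98 of 6754 elsewhere (one-sided Fisher's exact p = 0.0614). By the same exact test, the interval held 1 of the calls made without a block (p = 0.376) and 11 genes at an unadjusted p of 0.05 (p = 0.0403). Linkage and an effect of Sox10 cannot be told apart for the genes of this interval, and those to check first are 1700088E04Rik and, further off, Cbx7 (21 tested genes), Syngr1 (23) and Ift27 (35), of which Ift27 also passed without the block.

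Of 6 muscle genes seen first, 0 passed without the block; with it Myl1 and Popdc2 rose (differences 1.26 and 0.36, limma adjusted p = 0.0400 and 0.0245) and Mef2c fell (-1.01, 0.0221), while Myf5, Myog and Des did not pass. They led to the hypothesis that muscle lineage cells or transcription may be raised in Dom/Dom. It was tested on 22 measured skeletal muscle genes not looked at before. The blocked camera test gave p = 0.00125 with the preset correlation but p = 0.142 with an estimated one, and their mean was above 0 in 3 of 4 pairs, where 4 of 4 had been required. Their median difference was 0.06 (95% bootstrap interval 0.01 to 0.16), led by Myl4 (9.68 against 8.80) and Myh3 (8.18 against 7.52), with 0 past an adjusted p of 0.05 and 18 of 22 above 0, so the test did not decide.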
